A study of Rattus norvegicus with 4 samples.

How the data were processed

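Footpad skin from the hindlimb of Sprague Dawley rats was sequenced as 21-base digital gene expression tags, with 1 library for each of collection days 0, 3, 6 and 9. Per the labels' protocols, 4 irradiations of 10 Gy were given on days 1, 2, 4 and 5 with a 9 MeV electron beam at 500 cGy/min. Samples were grouped by the collection day in their titles. No animal, sex, batch or time of day is given in the labels.

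Each library came with a table of genes and a list of sequenced tags. Per the file headers and the values, the authors summed the copies of the tags assigned to a gene into a whole-number count and left out tags seen once in a library. The deposited column headed TPM held CPM values, that is counts scaled by the authors to the total of all tags seen at least 2 times, and was not scaled by transcript length. In the files 0 of the gene sums or tag copies departed from this reading in any library, and 0 of the scaled gene values did by more than 0.006 CPM plus 1 ppm of the value. Per the submitters' processing notes the assembly was Rnor_6.0. The aligner, the mismatches allowed and the annotation version are not given in the sources used here. Each tag stood under 1 gene. Counts were joined by the gene identifier of the files, which gave 18957 genes or UniGene-type entries, 11471 with a numeric gene ID and 7486 with a UniGene-type identifier alone. The latter held 21.0, 20.9, 21.0 and 20.4% of the counts on days 0, 3, 6 and 9. Of the gene IDs, 11247 were found in the reference table and 1152 had another symbol there. The symbols of the files were kept, and no coordinates were used.

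The libraries held 3592019, 3360368, 3556566 and 3442555 sequenced tags on days 0, 3, 6 and 9, of which 3482882, 3247997, 3445925 and 3326569 were seen at least 2 times. Gene counts were 56.9, 60.6, 57.1 and 58.7% of these, and the 20 most abundant genes held 21.9, 23.0, 24.3 and 23.3% of the gene counts. Scaling factors from the TMM method of edgeR 4.0.16 were 1.01, 1.02, 0.989 and 0.978. Ratios were taken between scaled counts with a prior count of 0.5 for a library, and an exact 95% Clopper-Pearson interval was computed from both counts. A library at 0 was given 3 counts as a floor, and its ratio is printed as at least that fold. Where the scale is not named, list medians are on the log2 scale.

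No test across samples was made, since neither edgeR's quasi-likelihood test nor DESeq2 can estimate the spread between animals from 1 library for each day. Genes were counted by size alone: at least 2-fold apart, at least 50 counts in the higher library, and an interval that excluded 1. The comparisons were each later day with day 0, day 6 with day 3, and day 9 with day 6. The 31 gene lists were fixed from knowledge of skin and radiation before the data were examined. A list was summarised by the median log2 ratio of its members with a mean of at least 10 counts, if there were at least 5, and by its percentile among 10000 random lists of the same size drawn from 20 expression bins. These percentiles describe the 4 libraries and are not p-values across animals, and list members may share regulation.

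Genes were named by a rule fixed at the same stage. For each later day against day 0 it took the 10 highest and 10 lowest genes past the size rule with at least 100 counts in the higher library and an established symbol. For each list it took the 2 to 4 members furthest apart with at least 50 counts in the higher library. It always took Cdkn1a, Mdm2, Mki67, Krt14, Krt10, Krt16, S100a8, S100a9, Il1b, Il6, Cxcl1, Col1a1, Cd207, Actb and Gapdh. LOC683313, Kdm5d, Ddx3y, Phlda3, Gadd45a and the entries for cytochrome oxidase and stefin-3-like were chosen after their values were seen, as were the genes whose tags differ between libraries. Some genes that the rule names are not reported here.

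The procedure was tested on counts simulated for day 3 against day 0, with known ratios given to 50 genes at each size. It called 48 of these at 2.5-fold, 50 at 4-fold and 50 at 8-fold. At 1.5-fold it called 0 of 50, a size that the 2-fold rule leaves out by design. The changed genes were drawn from those with a mean of at least 100 scaled counts, so recovery nearer the count floor was not tested. The procedure also called 2 of 18757 unchanged genes, a set that included genes below the count floor. A list shifted by 1.5-fold lay at percentile 100, and 0 of 23 unshifted lists stood apart. The simulated counts held counting error alone and no spread between animals, so they do not measure false calls between animals. Tag pairs 1 base apart were taken among tags with at least 50 copies in a library, and a pair was said to switch where the first member made up at most 5% of the pair in 1 library and the second at most 5% in another, with at least 30 copies of the pair in each. Alternatives covered the scaling (totals alone, DESeq2 1.42.0 size factors, totals without the 20 most abundant genes), the count floor (10, 200 or none), the interval bound, a prior count of 5, the authors' normalized value, the members and summary of a list, tags seen once, and the most abundant tag of each gene. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3. Sequencing reads were not used here, and counts of tags in no gene are given only in the closing section.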

Results

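Digital gene expression tag libraries were read from hindlimb footpad skin of Sprague Dawley rats, an outbred laboratory stock, in a model of radiation dermatitis, the skin injury that follows radiotherapy. In this assay each transcript is counted through a 21-base tag that begins at a CATG site near its 3' end. The labels describe 4 irradiations of 10 Gy on days 1, 2, 4 and 5 with 9 MeV electrons, and skin taken on days 0, 3, 6 and 9. Each day was measured with 1 library, so there was no replicate error and no test across animals. Every value compares 2 libraries, and every 95% interval covers counting error only. The libraries held 1982608, 1968034, 1967902 and 1952921 gene counts on days 0, 3, 6 and 9, and listed 15236, 15608, 14972 and 15501 genes.

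A gene was counted as higher or lower by a fixed rule of size: a ratio of scaled counts of at least 2, at least 50 counts in the higher library, and an interval that excluded 1. A gene list was said to stand apart when its median log2 ratio lay outside the central 95% of 10000 random lists matched on size and expression. Of the 31 lists, 24 had the 5 measured members this needed. The labels disagree in places: the description of the day 0 sample names day 1 as its collection day, and the descriptions of the later samples name 1 irradiation day each (days 2, 4 and 5), while the protocol gives 4 irradiations. The groups used here follow the sample titles.

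The first comparison asked how skin taken on day 3, after 2 irradiations by the protocol, differed from skin taken on day 0. The medians of p53 target genes, which p53 activates after DNA damage, and of dermal matrix genes were higher in the day 3 library, and those of cell division and cornified layer genes were lower. Ccng1, the p53 target cyclin G1, was 6.18-fold (5.48 to 7.01) higher, and Cdkn1a, the p21 inhibitor of the cell cycle, was 4.09-fold (3.6 to 4.67) higher. Cdk1, the kinase that drives entry into mitosis, was 2.37-fold (1.61 to 3.61) lower, and Krt10, the main acidic keratin of suprabasal epidermis, was 2.89-fold (2.80 to 2.99) lower. Col1a1, a chain of type I collagen, was 11.3-fold (10.8 to 11.9) higher.

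Of 18 measured p53 target genes, 7 were higher, 1 was lower and 10 passed neither side of the rule. Bbc3, the cell death gene PUMA, was 8.66-fold (5.72 to 14.2) higher, and Mdm2, which degrades p53, was 4.22-fold (2.86 to 6.60) higher, with counts of 30, 129, 125 and 164 on days 0, 3, 6 and 9. Plk2, a stress kinase seen through nearly 1 tag alone, was at least 23.5-fold higher, from counts of 0, 71, 59 and 3. The exception was Plk3, a stress kinase of the same family, which was 4.23-fold (2.88 to 6.55) lower. The list median was 0.70 on the log2 scale (percentile 99.96). Among 13 mitotic genes, 2 were lower and none was higher. These were Cdk1 and Birc5, a survivin gene active at cell division, which was 3.32-fold (1.91 to 6.35) lower, and the median was -1.59 (percentile 0). Mki67, the proliferation antigen, had 31 counts on day 0 and 10 on day 3, too few for the rule. Among 19 DNA replication genes 2 were lower: Rrm1, a subunit of ribonucleotide reductase, 3.20-fold (2.16 to 4.97) lower, and Mcm4, a helicase subunit, 7.77-fold (4.50 to 15.6) lower. The most abundant tag of Mcm4 was missing from the day 3 and day 6 libraries. The replication median was -0.94 (percentile 0), but over the 5 members with a mean of at least 50 counts it was -0.45 (percentile 9.19) and did not stand apart. Stmn1, a microtubule regulator of dividing cells that ranked among the 10 lowest genes, was 5.87-fold (3.98 to 9.24) lower.

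**Figure D1:**
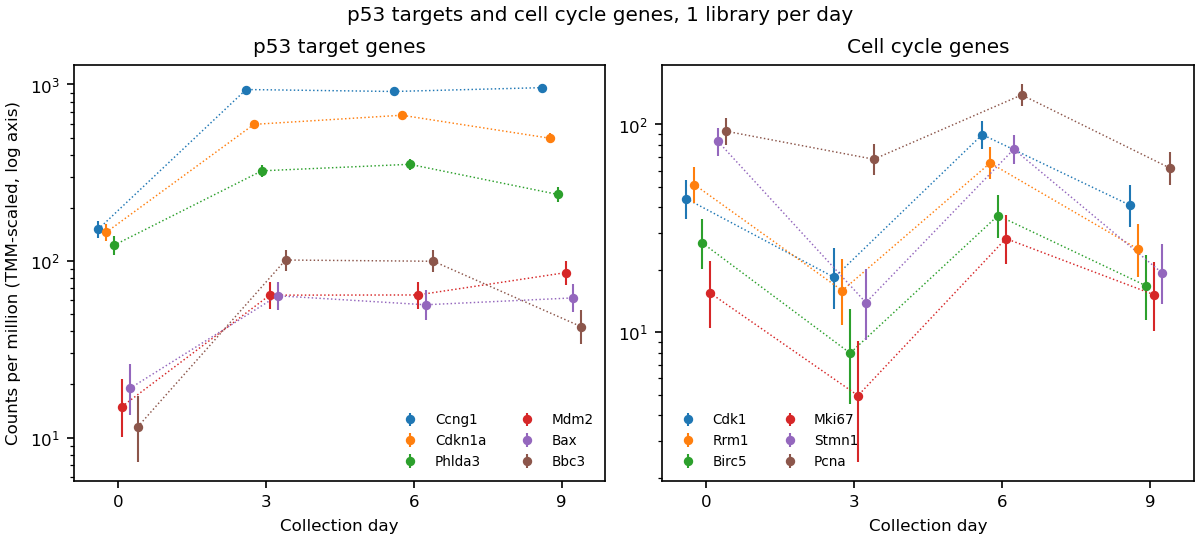
TMM-scaled CPM (log axis) of 6 p53 target genes and 6 cell cycle genes by collection day, with 1 library per day, points with 95% counting intervals and dotted lines that join separate libraries. Cdkn1a had 291, 1197, 1303 and 947 counts on days 0, 3, 6 and 9, while Cdk1 had 88, 37, 174 and 78.

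Cornified layer and differentiation genes had 4 lower and 1 higher member among 14, with a median of -0.77 (percentile 0). Krt2, a keratin of the upper epidermis, was 2.81-fold (2.46 to 3.23) lower, and Tgm1, the transglutaminase that crosslinks the cornified envelope, was 2.74-fold (2.21 to 3.45) lower. Krt9, the keratin of palm and sole skin, was the higher member, at 3.63-fold (3.03 to 4.38). Krt24, a keratin gene among the 10 lowest, was 6.73-fold (6.17 to 7.37) lower, from counts of 3841, 573, 295 and 269. Of 8 basal keratinocyte genes, Krt14 alone passed the rule and was 2.06-fold (1.68 to 2.53) lower, and the median of -0.33 did not stand apart, while that of all members did (-0.70). Of 12 stress keratin and alarm genes, 2 were higher and 2 were lower, with a median of -0.38 that did not stand apart, while it did with the most abundant tags alone (-0.73). Defb4, a beta-defensin, was 7.22-fold (4.32 to 13.7) higher, and Krt17, a keratin of injured skin, was 2.04-fold (1.75 to 2.38) lower.

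Dermal matrix genes were the list with the most members past the rule, with 13 of 18 higher and none lower and a median of 1.48 (percentile 100). Sparc, a collagen-binding glycoprotein, was 7.62-fold (7.41 to 7.84) higher, and Lox, the enzyme that crosslinks collagen, was 9.12-fold (6.04 to 15) higher. Matrix remodelling genes had a median of 0.70, with 2 of 12 higher and 1 lower, among them Mmp2 5.77-fold (5.39 to 6.18) higher and Acta2 2.14-fold (1.94 to 2.37) higher. Medians of some lists for other cell types were higher in the day 3 library as well. Adipocyte genes had a median of 1.4 with 4 of 8 higher, among them Adipoq, the fat hormone adiponectin, 10.8-fold (7.89 to 15.4) higher. Monocyte and macrophage markers had a median of 1.05 with 5 of 13 higher, among them the scavenger receptor Cd163, 7.67-fold (5.01 to 12.8) higher. Medians of 0.72 for skeletal muscle genes (4 of 10 higher), 0.75 for sweat gland genes (2 of 7 higher) and 0.71 for mast cell markers (2 of 6 higher) also stood apart, though with the most abundant tags alone muscle did not (0.48). Interferon response genes had a median of 0.77, with Irf7, a regulator of interferon genes, 5.13-fold (3.15 to 9.24) higher and Ifit2 2.48-fold (1.55 to 4.16) higher among 8.

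Circadian clock genes had a median of -1.15 (percentile 0), with 6 of 10 lower and 1, Arntl, higher. The time of day of collection is not given, so another hour on day 0 cannot be told apart from irradiation for this list. Nr1d1, a repressor in the clock loop, was 3.01-fold (2.53 to 3.6) lower, Dbp, a clock output factor, was 2.46-fold (2.22 to 2.73) lower, and the clock repressor Ciart (listed as RGD1566380) was 11.2-fold (5.53 to 30.6) lower. Medians that did not stand apart were -0.17 for DNA repair, -0.05 for oxidative stress, -0.09 for barrier lipids, -0.22 for immediate early and heat shock genes and 0.35 for endothelium. Those of nerve (0.55), ribosomal protein (0.43), respiratory chain (0.34) and reference genes (0.05) did not either, though nerve did with a prior count of 5 (0.54) or the authors' value (0.65). Within them, Fosb, an immediate early gene, was 11.0-fold (4.89 to 38.5) lower, Hmgcs1, an enzyme of cholesterol synthesis, was 2.73-fold (2.42 to 3.09) lower, and the reference gene Actb was 2.18-fold (2.06 to 2.31) lower, while Gapdh differed by 1.18-fold (1.11 to 1.25). Hbb, a beta-globin gene of red blood cells, was 42.3-fold (30.7 to 61.9) higher, from counts of 35, 1510, 104 and 579. Sts, steroid sulfatase, was 45.0-fold (22.1 to 134) higher, with nearly all copies of days 3 and 6 in 1 tag that had 2, 286, 437 and 7 copies. Eif2s3y, a Y-linked gene, was at least 39.1-fold higher, with counts of 0, 118, 92 and 130, and Klra17, a lectin-like receptor seen through 1 tag, was 16.7-fold (8.04 to 50.3) higher. The lowest genes included Kank1, 14.3-fold (7.14 to 38.8) lower, and Aplp2, 4.48-fold (3.46 to 5.95) lower, but the most abundant tags of both had at most 3 copies in the day 3 library. Naprt1, an enzyme of NAD synthesis, was 5.02-fold (3.66 to 7.18) lower, and Sec24c, Slc6a9 and Rhov were 5.14-fold, 4.64-fold and 4.42-fold lower. Among the highest genes, the membrane protein gene Itm2a was 12.3-fold (8.08 to 20.7) higher and C1qtnf6, a secreted C1q family member, was 12.0-fold (7.17 to 23.1) higher.

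In all, 456 genes were higher and 420 lower in the day 3 library by the rule, which is 16.4% of the 5342 genes with enough counts. With the authors' own normalized value plus 1 in place of scaled counts, and without the rule's interval, 500 were higher and 291 lower. The share of higher genes was 52.1% by counts and 63.2% by the authors' value.

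The comparison of day 6 with day 0 asked how skin differed 1 day after the last of the 4 irradiations by the protocol. The medians of the p53 target and dermal matrix lists were higher in the day 6 library, and those of skeletal muscle and sweat gland genes were lower. Ccng1 was 6.03-fold (5.34 to 6.84) higher and Cdkn1a was 4.60-fold (4.06 to 5.25) higher. Myl1, a myosin light chain of fast muscle, had counts of 2021, 5394, 0 and 4705 on days 0, 3, 6 and 9 and was at least 654-fold lower. Dhcr7, the last enzyme of cholesterol synthesis, was 2.61-fold (2.11 to 3.28) lower.

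Of 18 p53 target genes, 8 were higher and 1 lower, with a median of 1.39 (percentile 100). Bbc3 was 8.52-fold (5.62 to 14.0) higher, Phlda3 and Gadd45a passed the rule as well, and Plk3 was 2.06-fold (1.52 to 2.84) lower. Mitotic genes had a median of 0.47 (percentile 97.36) and 1 of 13 higher, Cdk1 at 2.03-fold (1.57 to 2.66). Mki67 had 55 counts on day 6 against 31 on day 0, a ratio of 1.81-fold (1.16 to 2.94) that did not pass. The replication median was 0.34, and the 1 of 19 members past the rule, Mcm4, was lower. The most abundant tag of Mcm4 was missing from the day 6 library. Neither the mitotic nor the replication list stood apart. With a prior count of 5 both did, at percentiles 98.36 and 97.73. Cornified layer genes had a median of 0.01, with Kprp, a proline-rich keratinocyte protein, 2.02-fold (1.91 to 2.15) higher and Tgm1 2.68-fold (2.15 to 3.37) lower among 14. Krt9 was 23.0-fold (11.1 to 68.5) lower, from counts of 153, 559, 6 and 40. Stress keratin and alarm genes had 2 higher and 2 lower members among 12 and a median of 0.04 that did not stand apart, while their mean of 0.83 did (percentile 99.81). Defb4 was 36.6-fold (22.7 to 68.0) higher, Il36g, an interleukin of keratinocytes, was 5.60-fold (3.81 to 8.75) higher, and Sprr1a, a cornified envelope precursor, was 4.48-fold (3.78 to 5.36) lower. LOC683313, described in the files as keratin 6A and chosen after its values were seen, was 12.7-fold (11.5 to 14.0) higher, with counts of 432, 1071, 5316 and 66660.

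Skeletal muscle genes had 6 of 10 members lower and none higher, with a median of -7.25, or -6.10 when counts of 0 are set to the floor of 3. The 10 lowest genes of this comparison were all muscle genes at 0 counts on day 6. Among them, Myh2, a fast myosin heavy chain, was at least 318-fold lower, Tnnt1, a troponin of slow muscle, was at least 121-fold lower, and Eno3, the muscle enolase, was at least 118-fold lower. The others were Myh1, Mybpc1, Cox6a2, Tnnc1, Tnni2 and Myot, with 730, 289, 282, 229, 229 and 189 counts on day 0. Sweat gland and simple epithelium genes had a median of -3.18, or -2.54 at the floor, with 3 of 7 lower. Krt19, a keratin of simple epithelium, was 14.9-fold (6.72 to 51.6) lower, Slc12a2, the chloride cotransporter of secretory cells, was 3.00-fold (2.23 to 4.14) lower, and the water channel Aqp5 was 2.71-fold (2.00 to 3.76) lower. Without the genes that were at least 4-fold lower on day 6 than in each other library, the count of genes past the rule was 1029 in place of 1090.

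Dermal matrix genes had 10 of 18 members higher and none lower, with a median of 1.01. Col1a1 was 6.51-fold (6.21 to 6.83) higher, Col3a1 was 5.12-fold (4.92 to 5.33) higher and Sparc was 5.71-fold (5.54 to 5.88) higher. Macrophage markers had a median of 0.88 with Cd68 and Cd163 higher among 13. Barrier lipid and cholesterol synthesis genes had a median of -0.95 (percentile 0.02), with 6 of 17 lower. Fdps, which makes farnesyl pyrophosphate, was 3.86-fold (3.07 to 4.93) lower, and Elovl3, a fatty acid elongase, was 2.97-fold (1.70 to 5.71) lower. Clock genes had a median of -0.68 with 4 of 10 lower, Nr1d1 by 3.03-fold (2.54 to 3.64), though their mean of -0.88 did not stand apart (percentile 3.47). Matrix remodelling, interferon, oxidative stress, mast cell, endothelial, nerve and adipocyte lists did not stand apart. Remodelling did with members of at least 50 mean counts (0.93, percentile 99.42), as did endothelium with the most abundant tags (0.78, percentile 99.23) and with all members (0.52, percentile 98.27). Within them, Txnrd1, a thioredoxin reductase, was 2.54-fold (2.04 to 3.20) higher and Vwf, the von Willebrand factor of endothelium, was 2.31-fold (1.74 to 3.12) higher. Actb was 4.27-fold (3.96 to 4.60) lower and Gapdh was 1.59-fold (1.49 to 1.69) lower, the latter short of the rule.

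**Figure D2:**
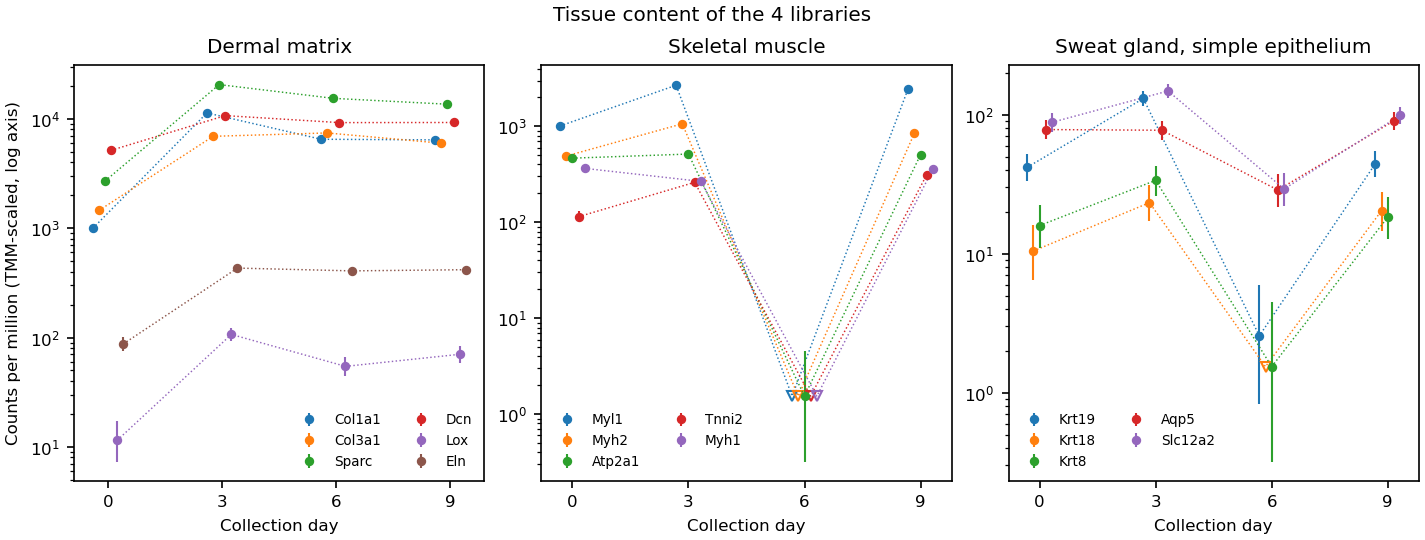
TMM-scaled CPM (log axis) of dermal matrix, skeletal muscle, and sweat gland or simple epithelium genes by collection day, with 95% counting intervals and open triangles at the 3-count floor for libraries with 0 counts. Myl1 had 2021, 5394, 0 and 4705 counts on days 0, 3, 6 and 9, while Col1a1 had 2001, 22815, 12663 and 12260.

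By the rule, 396 genes were higher and 694 lower on day 6, which is 20.6% of 5296 genes. Among the highest genes, Sts was 73.0-fold (36.1 to 217) higher through that 1 tag, and Ebna1bp2, a nucleolar protein gene, was 6.42-fold (3.98 to 11.5) higher, while C1qtnf6 and Itm2a were 7.77-fold and 6.58-fold higher. Abhd16a, a gene of the major histocompatibility region, was at least 39.1-fold higher through a tag that the day 0 and day 3 libraries lacked.

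The comparison of day 9 with day 0 asked how skin differed 4 days after the last irradiation by the protocol. The medians of stress keratin and alarm genes of injured epidermis, p53 target genes and dermal matrix genes were higher in the day 9 library, and that of DNA replication genes was lower. LOC683313, the row described as keratin 6A, was 162-fold (147 to 178) higher, and Krt17 was 9.97-fold (9.10 to 11.0) higher. S100a9, a calcium-binding alarm protein, was 27.1-fold (19.5 to 39.97) higher, and Defb4 was 113-fold (70.6 to 209) higher. Mcm2, a subunit of the replication helicase, was 2.29-fold (1.4 to 3.95) lower.

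Stress keratin and alarm genes had 10 of 12 members higher and none lower, with a median of 3.56 (percentile 100). Krt16, the partner of keratin 6, was at least 83.6-fold higher, from counts of 0, 0, 37 and 239. These are assigned tags only, and 39.4 to 43.1% of tags seen at least 2 times stood in no gene. A count of 0 therefore does not show that Krt16 was absent. Il24, a cytokine of the interleukin-10 family, had 0 counts on days 0, 3 and 6 and 75 on day 9, at least 26.2-fold higher. S100a8, the partner of S100a9, was 3.25-fold (2.27 to 4.84) higher, Il36g was 14.0-fold (9.75 to 21.5) higher and Sprr1a was 4.13-fold (3.81 to 4.49) higher. Other genes among the 10 highest were Stfa3, a cystatin, at least 100.4-fold higher, and Arg1, arginase 1, 32.2-fold (19.0 to 65.4) higher. Ankrd1, an ankyrin repeat protein gene, was 28.5-fold (12.2 to 119) higher, and Ca2, a carbonic anhydrase, was 25-fold (13.6 to 58.4) higher. Fam111a, a nuclear protease gene, was at least 46.5-fold higher, Eif2s3y was at least 45.5-fold higher and Hbb was 17.1-fold (12.3 to 25.2) higher. Basal keratinocyte genes had a median of 0.18 that did not stand apart. Cornified layer genes had a median of -0.28 that did not stand apart, with 3 of 14 lower. Of these, Krt10 was 2.26-fold (2.19 to 2.33) lower and Krt2 was 3.89-fold (3.33 to 4.58) lower, and the other was Krt9. Klk7, a protease of desquamation, was 2.21-fold (1.99 to 2.45) higher.

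**Figure D3:**
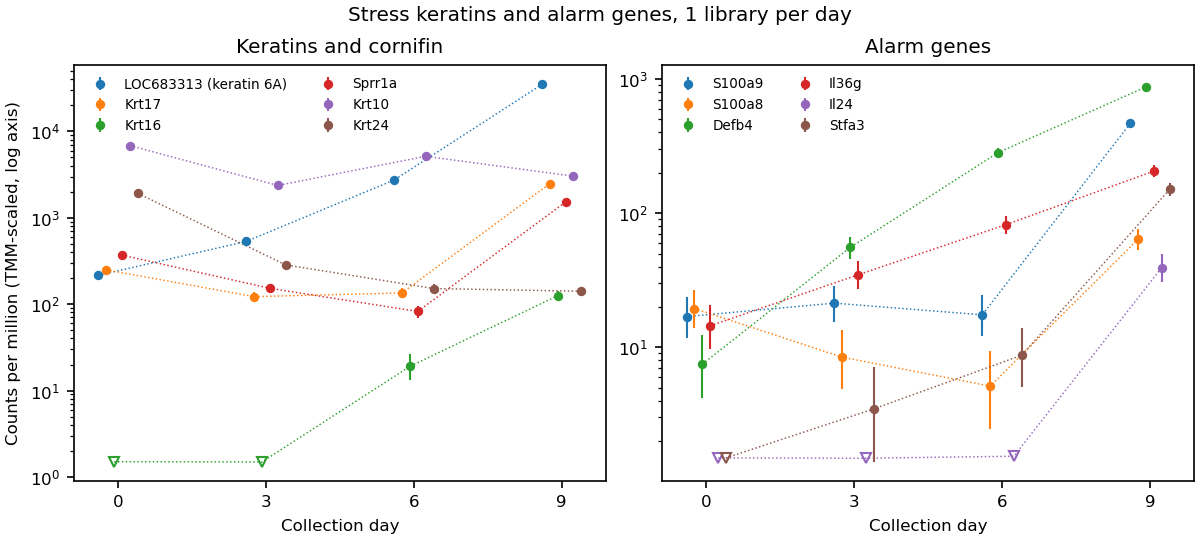
TMM-scaled CPM (log axis) of keratin, cornifin and alarm genes by collection day, with 95% counting intervals and open triangles at the 3-count floor for libraries with 0 counts. The row described as keratin 6A (LOC683313) had 432, 1071, 5316 and 66660 counts on days 0, 3, 6 and 9, and S100a9 had 34, 43, 34 and 891.

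The p53 target genes had 8 of 18 members higher and none lower on day 9, with a median of 1.44. Ccng1 was 6.33-fold (5.61 to 7.19) higher, Mdm2 was 5.66-fold (3.87 to 8.78) higher, Cdkn1a was 3.41-fold (2.99 to 3.91) higher and Bbc3 was 3.64-fold (2.30 to 6.16) higher. DNA replication genes had 5 of 19 members lower and a median of -1.02 (percentile 0). Mcm6 was 2.21-fold (1.63 to 3.06) lower and Prim1, a primase subunit, was 2.22-fold (1.34 to 3.89) lower. None of 13 mitotic genes passed the rule and their median did not stand apart, while that of all members did (-0.68). The median of 5 DNA repair genes, -0.73 (percentile 3), did not stand apart, though with a prior count of 5 it did (percentile 2.46).

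Oxidative stress response genes had 6 of 13 members higher and a median of 0.59 (percentile 98.91). Slc7a11, the cystine transporter, was 12.1-fold (6.28 to 30.6) higher, and Hmox1, heme oxygenase 1, was 4.26-fold (2.79 to 6.91) higher. Dermal matrix genes had 8 of 18 members higher and a median of 0.95, Col1a1 by 6.43-fold (6.13 to 6.75) and Eln, elastin, by 4.76-fold (4.05 to 5.66). Matrix remodelling genes had a median of 0.72, with Adamts1, a secreted metalloproteinase, 8.28-fold (5.46 to 13.7) higher and Mmp2 3.97-fold (3.70 to 4.27) higher among 12, though 5 members with at least 50 mean counts did not stand apart (percentile 96.67). Macrophage markers had a median of 0.82 with 3 of 13 higher, and muscle genes a median of 0.79 with 4 of 10 higher. Barrier lipid genes had 6 of 17 members lower and 1 higher, with a median of -0.52. This did not stand apart with members of at least 50 mean counts (-0.16, percentile 16.46) or with all members (-0.34, percentile 4.18). Dhcr7 was 5.65-fold (4.22 to 7.82) lower, Elovl3 was at least 15.9-fold lower with 0 counts, and Hmgcs1 was 3.63-fold (3.17 to 4.19) lower. Clock genes had a median of -1.06 with 5 of 10 lower, Tef by 3.18-fold (2.5 to 4.12). Immediate early, interferon, mast cell, endothelial, sweat gland, adipocyte and nerve lists did not stand apart, though the adipocyte mean of 0.75 did. Of 13 immediate early and heat shock genes, 3 were higher and 2, Fosb and Hspa1b, were lower, with Atf3, a stress transcription factor, 3.51-fold (2.5 to 5.10) higher. Of 6 mast cell markers, 1 was higher and 1, Cma1, was lower. The higher one was Cpa3, the mast cell carboxypeptidase, at 2.36-fold (1.86 to 3.03).

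By the rule, 571 genes were higher and 560 lower on day 9, which is 21.2% of 5334 genes. The lowest genes included Comp, a matrix protein gene, 25.9-fold (12.6 to 77.2) lower, Krt24, 13.6-fold (12.0 to 15.5) lower, and Dapl1, a gene expressed in differentiating epithelium, 9.34-fold (8.15 to 10.8) lower. Tfap2b, a transcription factor, was 7.82-fold (5.96 to 10.6) lower, Phgdh, the first enzyme of serine synthesis, was 6.91-fold (4.40 to 11.9) lower, and Pdcd4 was 6.78-fold (6.01 to 7.70) lower. Hs3st6 and Nkain3 were 7.98-fold and 6.88-fold lower. Ddx39b, a helicase gene of the major histocompatibility region, had counts of 467, 481, 5 and 6, and Gnl1, of the same region, had 105, 29, 0 and 0. The most abundant tags of both were missing from the day 6 and day 9 libraries. With the day 3 library as the comparator in place of day 0, 331 genes were higher and 237 lower.

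Day 6 was next compared with day 3, to set the skin before and after the protocol's second pair of irradiations side by side. The medians of cell division and cornified layer genes were higher in the day 6 library, and those of muscle, sweat gland, fat, macrophage and mast cell genes were lower. Mki67 was 5.46-fold (2.87 to 12.5) higher, Cdk1 was 4.81-fold (3.4 to 7.14) higher and Krt10 was 2.17-fold (2.10 to 2.25) higher. Adipoq was 12.2-fold (8.76 to 18.0) lower. Myh2 was at least 689-fold lower.

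The mitotic list had 3 of 13 members higher and a median of 2.16, or 1.83 with counts of 0 at the floor. Birc5 was 4.48-fold (2.64 to 8.46) higher. The replication list had 5 of 19 members higher and a median of 1.09, with Rrm1 4.06-fold (2.77 to 6.26) higher and Tk1, thymidine kinase, 2.58-fold (1.65 to 4.23) higher. Cornified layer genes had 4 of 14 higher and 1 lower and a median of 0.82, with Kprp 2.34-fold (2.20 to 2.49) higher and Krt9 83.3-fold (41.1 to 246) lower. Stress keratin and alarm genes had a median of 0.41 (percentile 99.25), with Defb4 5.07-fold (4.15 to 6.29) higher and Il36g 2.36-fold (1.78 to 3.18) higher among 12. This list did not stand apart with single tags restored (0.10, percentile 62.7) or with all members (0.27, percentile 97.3). The p53 target median of 0.15 did not stand apart, and Cdkn1a differed by 1.13-fold (1.04 to 1.22).

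Lower lists were muscle, with a median of -7.75 and 8 of 10 lower, sweat gland, with -4.24 and 4 of 7 lower, and adipocyte genes, with -1.19 and 4 of 8 lower. With counts of 0 at the floor, the muscle and sweat gland medians were -6.77 and -3.22. Mast cell markers (-0.83, 2 of 6 lower), macrophage markers (-0.60, 2 of 13 lower), interferon genes (-0.67, 1 of 8 lower) and dermal matrix genes (-0.37, 2 of 18 lower and 1 higher) also lay below, though none of these 4 stood apart with the mean in place of the median, nor did the cornified layer list, or interferon genes with the most abundant tags (-0.38). Cpa3 was 2.04-fold (1.70 to 2.45) lower, Aif1, a macrophage marker, was 2.61-fold (2.18 to 3.16) lower, Irf7 was 2.53-fold (1.72 to 3.85) lower and Fmod, fibromodulin, was 3.21-fold (2.94 to 3.52) lower. By the rule, 145 genes were higher and 344 lower on day 6, a higher share of 29.7%. The authors' value, again without the interval, gave 84 and 415, a higher share of 16.8%. Without the genes that were at least 4-fold lower on day 6 than in each other library, 412 genes passed in place of 489.

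The last comparison set day 9 against day 6, both after the last irradiation by the protocol. The median of stress keratin and alarm genes was higher in the day 9 library, those of cell division genes were lower, and those of muscle and sweat gland genes were higher. LOC683313, the row described as keratin 6A, was 12.8-fold (12.4 to 13.1) higher, Krt17 was 18.4-fold (16.3 to 21) higher and S100a9 was 26.4-fold (19.0 to 38.8) higher. Rrm1 was 2.58-fold (1.85 to 3.70) lower and Stmn1 was 3.89-fold (2.72 to 5.79) lower.

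Of 12 stress keratin and alarm genes, 9 were higher, with a median of 3.15, among them Sprr1a at 18.5-fold (15.8 to 21.9) and Serpinb2, a protease inhibitor of keratinocytes, at 6.65-fold (5.32 to 8.47). Of 19 replication genes, 7 were lower, with a median of -1.37, among them Mcm2 at 3.90-fold (2.49 to 6.56). The mitotic median was -0.88, with Cdk1 and Birc5 lower among 13. Cornified layer genes had a median of -0.34, with Krt2 2.96-fold (2.52 to 3.5) lower and Tgm1 2.07-fold (1.65 to 2.63) higher among 14, while the mean of -0.027 did not stand apart (percentile 31.85). Matrix remodelling genes had a median of 0.75 with 4 of 12 higher, among them Adamts1 at 4.35-fold (3.13 to 6.26) and Mmp14 at 5.10-fold (2.74 to 11.2). With members of at least 50 mean counts alone, 5 genes were left and that median was -0.23 and did not stand apart. Immediate early genes had a median of 0.63 with Atf3 6.90-fold (4.44 to 11.7) higher and Ier3 5.84-fold (3.5 to 10.9) higher among 13, while the mean of 0.73 did not stand apart. Barrier lipid genes had a median of 0.35, with 1 of 17 higher and 1 lower, but did not stand apart by the mean (0.060, percentile 45.43) or with the most abundant tags (0.33, percentile 97.23).

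Muscle genes had a median of 7.84, or 7.23 with counts of 0 at the floor, and 8 of 10 higher. Sweat gland genes had a median of 3.37, or 1.87 at the floor, and 3 of 7 higher, and adipocyte genes a median of 0.53 and 1 of 8 higher. The adipocyte list did not stand apart with members of at least 50 mean counts (0.40), with all members (0.53) or by the mean (1.14). All 3 measured class II histocompatibility genes of the dendritic cell list were higher, RT1-Db1 at 3.09-fold (2.60 to 3.69), RT1-Da at 3.18-fold (1.82 to 6.11) and RT1-Ba at 2.71-fold (2.27 to 3.25). The tags of RT1-Db1 and RT1-Ba differed between libraries. The p53 target and dermal matrix medians of -0.07 and -0.05 did not stand apart. Bbc3 was 2.34-fold (1.80 to 3.08) lower and Col1a1 differed by 1.01-fold (0.988 to 1.04). By the rule, 515 genes were higher and 224 lower on day 9, and 661 in place of 739 passed without the genes that were at least 4-fold lower on day 6 than in each other library.

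**Figure D4:**
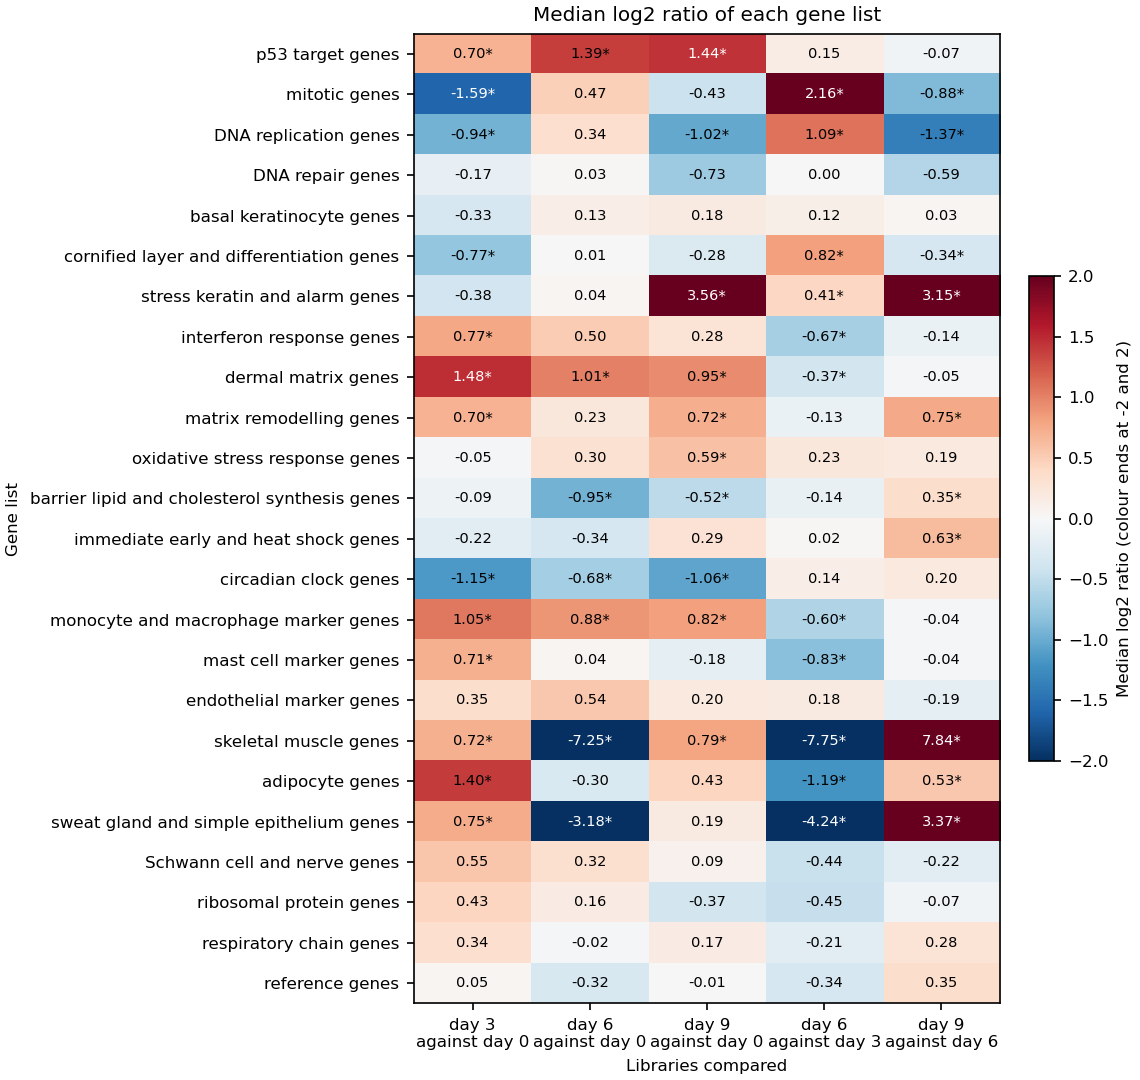
Median log2 ratio of the measured members of each of 24 gene lists in 5 library comparisons, with colour from -2 to 2 and an asterisk where the median lay outside the central 95% of 10000 matched random lists. The p53 target list stood at 0.70, 1.39 and 1.44 against day 0, and the stress keratin and alarm list at 3.56 on day 9 against day 0.

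Further lists had too few measured members for a median. The cytokine and chemokine list had 4, among them Il33, an alarm cytokine, 2.55-fold (1.75 to 3.84) higher on day 3 and 2.06-fold (1.38 to 3.15) higher on day 9 than on day 0. Il1b had counts of 6, 3, 5 and 35 and Cxcl1 had 0, 3, 0 and 11, both too few for the rule, and Il6 and Cd207 were listed in none of the 4 libraries. Neutrophil markers had 2 measured members, of which Ncf4 was 2.16-fold (1.32 to 3.72) higher on day 9 than on day 0. Dendritic cell markers had 3, the red blood cell list had Hbb alone, and the T and NK cell, B cell and hair follicle lists had none. At this depth a library with 0 counts was given a floor of 3 counts. Counts of Gapdh were 2515, 2148, 1537 and 2377 and those of Actb 3848, 1774, 876 and 2316.

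Tag sequences differed between the libraries, and the labels do not say whether a library came from 1 animal or a pool. Among 484 pairs of tags 1 base apart, 28 switched fully between libraries, so that a library held one member and hardly any of the other. The day 0 library alone held the other member in 10 of them, the day 3 library alone in 1, and the day 6 and day 9 libraries in 0. Of these 10, 7 involved rows described as cytochrome oxidases, whose genes lie on the mitochondrial genome and are inherited together. The rest had both members in no gene. Cytochrome oxidase II was read through CATGAGCCATCCCTTCACTAG with 2, 4345, 3960 and 6029 copies and through CATGAGCCGTCCCTTCACTAG, which differs at 1 base, with 3606, 2, 2 and 3. Cdkn1a was read through CATGTATTTTGGTCCCCTCCC with 142, 1100, 0 and 397 copies and through CATGTATTTTGGTCCCTTCCC with 118, 0, 1206 and 457, and its summed count holds both. With its most abundant tag alone, the day 3 to day 0 ratio turned to -7.87 (log2). The Y-linked genes Eif2s3y and Kdm5d together had 0, 143, 129 and 156 copies, tags seen once included. The entry for Ddx3y, also Y-linked, had 1029, 739, 469 and 870 counts, and the files hold no entry for its X-linked relative Ddx3x. Kdm5d and Ddx3y were looked up after the values of Eif2s3y were seen.

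**Figure D5:**
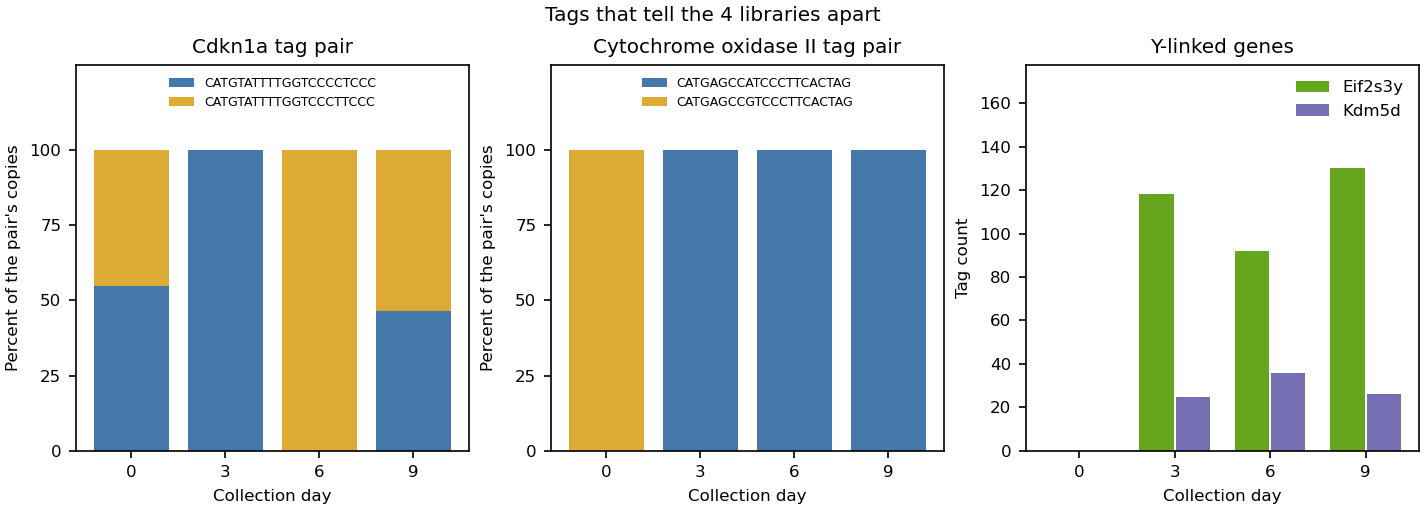
Stacked bars show the percent of a pair's copies held by each of both tags 1 base apart, for Cdkn1a and for cytochrome oxidase II, and plain bars show the counts of the Y-linked genes Eif2s3y and Kdm5d, by collection day. Eif2s3y had 0, 118, 92 and 130 counts and Kdm5d had 0, 25, 36 and 26 on days 0, 3, 6 and 9.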

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

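All tests in this part were chosen after the result was seen. Signals in data that no comparison used were found in the lists of sequenced tags. The share of tags seen at least 2 times that stood in no gene was 43.1% on day 0, 39.4% on day 3, 42.9% on day 6 and 41.3% on day 9. Among the 40 most abundant of these tags, the 4 with the largest day 9 to day 0 ratio in either direction were as follows, in CPM on days 0, 3, 6 and 9. CATGGTGATAGTCTAATAAAG had 13.8, 231.8, 1441.4 and 8504.9, and CATGAAATTATATTAAAAAAC had 490.7, 1328.8, 1409.5 and 2560.3. CATGAACGTCAAGCTGGCCCT had 15808.5, 4875.6, 8751.8 and 2430.1, and CATGTTGAAATCAAAAAAAAA had 5514.1, 2553.9, 3461.2 and 1124.9. Their genes are not known from the files. Of the 28 pairs of tags 1 base apart that switched fully between libraries, 8 had at least 1 member in no gene.

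The first pattern weighed was the day 6 library without skeletal muscle transcripts. Of 6 muscle genes with a mean of at least 100 counts in the other libraries, 6 were at least 8-fold lower on day 6 than in the lowest of those, which restates the pattern and leaves open whether the sample held no muscle tissue. Sequence variants would remove 1 tag of a gene, but the tags other than the most abundant were 78.9-fold (26.7 to 385) lower on day 6 than on day 3 when summed, which argues against variants. An effect of irradiation on muscle cannot be told apart from a sample without muscle, since day 6 has 1 library and the labels disagree on the irradiations each sample had; the muscle median on day 9 stood at 0.79 against day 0. Krt9, a keratin of sole skin, had 6 counts on day 6 and 153 on day 0, so the skin site taken might differ as well, which was not tested. By the rule Krt9 was also lower on day 9 than on day 0, so the same doubt holds for the day 9 library.

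The second pattern was the day 0 library apart in tag variants. It alone held the other member in 10 switching pairs, against at most 1 for any other library, which restates the pattern. Of the 10, 7 lie in mitochondrial genes inherited together and count as 1 difference, as an animal of another maternal line would give. The rest lie in no gene, and no switching pair in a gene with a symbol set the day 0 library alone apart. Sequencing error or shallow depth would leave traces of the missing member, which made up 215 ppm of its pair (26 of 121200 copies in 16 cases). These cases were picked for many copies of the pair and a missing member of at most 5%. That choice left out shallow depth and held the missing share low, so the value cannot decide on either. Pairs with fewer copies were not tested. The Y-linked genes Eif2s3y and Kdm5d had 0 copies on day 0 and 143, 129 and 156 on the later days, but whether the day 0 animal lacked a Y chromosome cannot be told, since the Ddx3y entry had 1029 counts on day 0 and no entry for Ddx3x shows whether X-linked tags fill it. Differences between day 0 and the later days could hold differences in ancestry between animals or pools, and no biological explanation by irradiation was tested for these tags. Pairs also switched between later libraries: 6 between days 3 and 6, 7 between days 3 and 9, and 4 between days 6 and 9. Comparisons among the later days could hold such differences as well.

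The third pattern was a lower median of matrix genes in the day 0 library. Less dermis in the day 0 sample would raise markers of 5 other dermal cell types alike on the later days, but the matrix median exceeded the median of 40 such markers by 0.66 (0.14 to 1.46), 0.58 (0.19 to 1.79) and 0.52 (0.06 to 1.27), with a lowest bound of 0.060. Against the 19 endothelial, nerve and mast cell markers alone, the first version of this test, the differences were 0.93, 0.62 and 0.86. This cannot decide on less dermis, since the matrix list was weighed because of its shift. The intervals also resample genes within single libraries and hold no spread between samples. The 40 markers were themselves higher by medians of 0.82, 0.43 and 0.42, so less dermis stays open, at least as a part. The matrix median without the most abundant tag of each gene was 1.501 (0.84 to 2.13) over 14 genes on day 3 against day 0, which argues against sequence variants. An effect of irradiation on the dermis, with a matrix median of 0.95 on day 9, cannot be told apart from differences between animals or skin pieces, since each day has 1 library.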

How the results depend on the processing

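Single tags restored, the most abundant tag alone, and the sets without some genes or with another comparator were chosen after the data were examined, and all other choices before the data were examined. No paired analysis was possible because each group held 1 library, and no replicate could be left out. Of 51 list medians that stood apart, 35 did so under every alternative that gave a value, and 477 of 499 values from 10 alternatives kept the call. For 11 of the 51, members of at least 50 mean counts were too few for a value. Of 69 medians that did not stand apart, 16 did under at least 1 alternative. Among them, on day 6 against day 0, were mitotic genes (higher) with a prior count of 5, the authors' value and single tags restored (0.40, 0.39 and 0.47) and replication genes with a prior count of 5 and the most abundant tag (0.33 and 0.41). The others were nerve, stress keratin and basal lists on day 3 against day 0, endothelial, remodelling and stress keratin lists on day 6 against day 0, and repair, mitotic and adipocyte lists on day 9 against day 0. On day 6 against day 3 they were respiratory, repair and barrier lipid lists, and on day 9 against day 6 reference and repair lists. Of 4137 alternative values for 591 ratios of named genes, 4010 lay within the counting interval, 126 outside it (65 with the most abundant tag alone) and 1 turned. That was Cdkn1a on day 3 against day 0, at -7.87 (log2) with its most abundant tag alone, because that tag was 1 member of a switching pair. Median log2 ratios of genes with enough counts ranged from -0.063 to 0.049 over the scalings.

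Counts of genes past the rule are given for day 3, day 6 and day 9 against day 0, day 6 against day 3 and day 9 against day 6. They were 1917, 2362, 2319, 1386 and 1807 with a floor of 10 counts, 2228, 2722, 2636, 1650 and 2098 with none, and 272, 320, 353, 140 and 218 with a floor of 200. They were 336, 539, 474, 219 and 321 when the interval bound itself had to reach 2-fold. These settings admit or drop genes by construction. With day 3 in place of day 0, day 9 gave 568, and the cause was not tested.

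Of the lists, 8 stood apart on day 3 against day 0 with members of at least 50 mean counts (fewer members), and on day 6 against day 3 that rule and the mean gave 7 and 7. Calls were lost as follows (log2), and the cause was not tested. With members of at least 50 mean counts: replication day 3 against day 0 -0.45, remodelling day 9 against day 0 0.72, barrier lipid day 9 against day 0 -0.16, adipocyte day 9 against day 6 0.40, and remodelling day 9 against day 6, which turned, -0.23. With all members: barrier lipid day 9 against day 0 -0.34, stress keratin day 6 against day 3 0.27, adipocyte day 9 against day 6 0.53. With single tags restored: stress keratin day 6 against day 3 0.10. With the most abundant tag: muscle day 3 against day 0 0.48, interferon day 6 against day 3 -0.38, barrier lipid day 9 against day 6 0.33. With the mean, clock day 6 against day 0 gave -0.88. For day 6 against day 3 it gave cornified 0.24, interferon -0.47, matrix -0.46, macrophage -0.57 and mast cell -0.84. For day 9 against day 6 it gave cornified -0.027, barrier lipid 0.060, immediate early 0.73 and adipocyte 1.14. At this depth 0 counts and 3 counts cannot be separated, and changes under 2-fold were outside the rule.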

Other observations

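An entry described as stefin-3-like, a cysteine protease inhibitor, had 86, 96, 97 and 5142 counts on days 0, 3, 6 and 9 and was 62.4-fold (50.7 to 78.6) higher on day 9 than on day 0. It was chosen after its values were seen, and its most abundant tag had 86, 83, 88 and 3226 copies. Of the switching tag pairs, 8 had a member in no gene. Both members were present in 21 cases, at 25.8 to 57.9% (median 50.7%) for the first member. In the comparisons of the report, genes whose dominant tag differed between the libraries made up 9, 14, 8, 11 and 4 of the genes past the rule. Such a gene needed at least 5 counts in each library compared. Its dominant tag had to hold at least 50% of the counts in a library and at most 5% in the other. Genes with fewer counts in either library, such as Gnl1 on days 6 and 9, could not be counted. These numbers are therefore not the full extent of tag differences.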
